A study of Homo sapiens with 8 samples.

How the data were processed

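Gene expression was measured in DU145 cells 3 days after transfection with a miR-205 precursor or a negative control precursor at 20 nM, on 8 Illumina bead arrays, 4 per group. The deposited tables of each array hold, per the file headers, a mean bead intensity and a detection p-value for each of 22184 probes. The submitters' processing notes name BeadStudio and no version. The intensity columns as deposited were not yet equal between arrays, with means from 270.6 to 446.2, and were taken as signals without normalization between arrays. A table of the whole series, used as an alternative, holds the authors' processed intensity values for 11677 of the probes. Its 8 columns each correlated best with their own array (lowest r of log2 values 0.989), and its values follow a linear scale with column medians from 177.5 to 178.4. How the authors scaled it is not given in the sources used here.

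The bead signals were corrected for background and normalized with limma's neqc (normexp fitted through the detection p-values, an offset of 16, then quantile normalization and log2), in limma 3.58.1 under R 4.3.3. A probe was tested if its detection p was under 0.01 on all 4 arrays of at least 1 group, which left 12341 probes of 10982 genes. The groups were compared with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05, and without the experiment as a block. A gene is represented by its brightest probe over the 8 arrays, and 1138 genes had more than 1 tested probe. Fold changes are miR-205 over control. Where all arrays of a group were under the detection threshold, the fold is a lower bound against the lowest detected signal or the probe's own, whichever was higher on each array. Of 18197 symbols in the files 14122 were current in the RefSeq gene table of assembly GRCh38.p14, 2914 were updated through a single synonym, and 131 with several candidates and 1030 without a match were kept as in the files. The files name no genome build, so no coordinates are given.

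Arrays of the 2 groups share replicate numbers. Deviations of the arrays from their group means correlated across probes between 0.428 and 0.624 for arrays of the same number, between -0.533 and 0.332 for arrays of different numbers, and 8 of 8 arrays correlated best with their own number. The numbers were therefore taken to pair the arrays, a pairing that comes from the data together with the series' statement of 4 independent experiments. The fit with the experiment as a block stands beside a result where it changes a call or moves a count by over 1.5 times.

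For 22 gene lists fixed before the data were examined, the text gives the members past the threshold over all probes and adjusted over the list alone, the median log2 fold change, and camera with a preset correlation of 0.01, adjusted over the lists. The lists are reported miR-205 targets, epithelial junction and identity, mesenchymal genes, basement membrane, motility and matrix proteases, interferon-stimulated genes, cytokines and NF-kB targets, G1/S, G2/M, CDK inhibitors with p53 targets and apoptosis, cholesterol and fatty acid synthesis, unfolded protein response, hypoxia and glycolysis, autophagy and lysosome, TGF-beta targets, microRNA machinery, ribosomal proteins, the mitochondrial respiratory chain, and markers of luminal prostate, fibroblasts, leukocytes and endothelium. Camera passed 6 lists without the block and 8 with it. With an estimated correlation none passed, in either fit. Fry is given in its directional form, adjusted over the lists. It passed motility alone without the block (adjusted p = 0.0434) and epithelial genes alone with it (0.0259). Without the block it gave 0.148 for epithelial genes, 0.176 for reported targets, 0.205 for TGF-beta targets, 0.250 for ribosomal proteins and 0.599 for cytokines and G2/M genes. The mixed form, which takes changes in either direction, passed epithelial genes (0.00620), basement membrane and motility (0.00608 each) without the block. With the block the mixed form passed more lists, among them cytokines, TGF-beta targets, hypoxia and interferon-stimulated genes (0.00797 each). It did not pass G2/M genes (0.1375) or ribosomal proteins (0.174) in that fit.

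Genes were named by a rule fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap, a fixed set of genes (ZEB1, ZEB2, PRKCE, ERBB3, E2F1, E2F5, CHN1, EZH2, CAV1, IL6, CDH1, VIM, FN1, LAMB3 and ITGB4, with 1 more), and from each list up to 4 members that passed and 2 that did not, by size. Of the genes that the rule takes, 2 are not reported here, and they stay in the counts of genes and lists. Only 8 genes passed without the block. Applying the rule to the fit with the block, with the requirement of the same direction in all 4 experiments in place of groups that do not overlap, was chosen after the values were seen.

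The procedure was tested on simulated data made from the real arrays' means and spread, for 12341 probes and this comparison. Without the block 29.9% of probes changed 1.5-fold, 85.1% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, with 1 false call, and with the block 53.7%, 88.1% and 98.5%, with 11 false calls. With no change there were 0 calls in either fit. Of 100 unchanged gene lists 4 had a camera p under 0.05 without the block and 3 with it. The simulated probes varied independently of each other, so this does not test camera where the members of a list correlate. In the data without the block, the estimated correlation ran from -0.0801 for luminal prostate markers to 0.655 for G2/M genes. The simulation also gave a probe the same spread on every array. In the data miR-205 array 1 had a mean squared deviation from its group of 0.182, and control array 1, the next highest, 0.0766. False calls of genes were therefore not tested for such uneven arrays or for probes that shift together.

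Alternatives changed the background correction, the scaling between arrays, the offset, the filter, the source of the values, the block, the array weights, the variance prior, the choice of probe, the threshold and the arrays included. The closing text gives their effect. A test of miR-205 seed matches in 3' untranslated regions was not run because no transcript sequences were used here.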

Results

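Gene expression was measured on 1-colour Illumina bead arrays in DU145 cells, a human prostate carcinoma line. The cells had been given a synthetic precursor of the microRNA miR-205, or a negative control precursor, at 20 nM 3 days earlier. Each group held 4 arrays, numbered 1 to 4 after 4 independent experiments, and arrays of one number are called an experiment here because they deviated from their group means together. Between 12617 and 13146 of the 22184 probes were detected per array, and the mean raw signal ran from 270.6 on miR-205 array 1 to 446.2 on miR-205 array 4. The filter on dim probes left 12341 probes of 10982 genes, and the number of arrays limits the precision of every value below. Pearson's r of the log2 raw signals across probes lay between 0.969 and 0.996 for all pairs of arrays, so no array was a copy of another. The first principal component held 53.2% of the variance and set the arrays of experiment 1 apart, with miR-205 array 1 at -54.28, control array 1 at -13.66 and the other 6 arrays between 5.43 and 20.12.

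**Figure D1:**
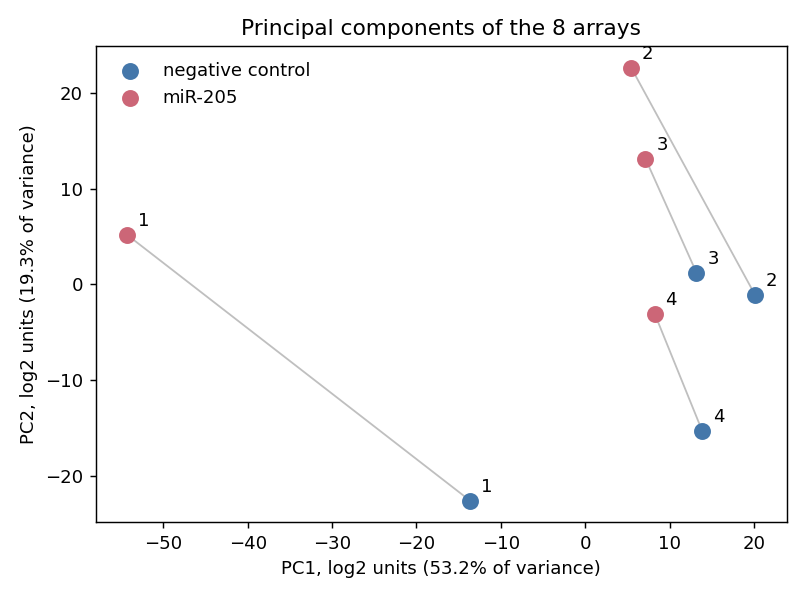
Principal components of the 8 arrays over the tested probes, with PC1 (53.2% of the variance) on the horizontal axis and PC2 (19.3%) on the vertical axis, both in log2 units. Points are arrays, blue for negative control and red for miR-205, numbered by experiment, and a grey line joins the arrays of an experiment; miR-205 lies above the control of its own experiment on PC2 in all 4 experiments.

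The first comparison asked which genes miR-205 changes in these cells. Of the genes that passed, 8 rose without regard to experiment, among them a protease, adhesion molecules and receptors. MMP1, the interstitial collagenase, rose by 2.57 ± 0.25 on the log2 scale (SE, n = 4 arrays per group; limma adjusted p = 0.0197), a fold of 5.93. CEACAM6, an adhesion molecule of the carcinoembryonic antigen family, rose by 3.23 ± 0.44, from a signal detected on 1 of the 4 control arrays to one detected on all 4 miR-205 arrays. NTSR1, the neurotensin receptor, rose by 2.51 ± 0.33, and ITGA2, the alpha-2 subunit of a collagen-binding integrin, by 1.41 ± 0.19. BSPRY rose by 1.23 ± 0.16, F2RL1, the protease-activated receptor 2, by 1.16 ± 0.16, and LPIN1, a phosphatidate phosphatase, by 0.96 ± 0.13. C2orf15 was below the detection threshold on all 4 control arrays and detected on all 4 miR-205 arrays, at least 1.55-fold higher. The limma adjusted p of each of these 7 genes was 0.0493.

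Those 8 genes, all raised, were the whole set past an adjusted p of 0.05 in limma without the experiment as a block, and in each of them the 4 miR-205 values lay above the 4 control values. None was lowered at that threshold, while at an unadjusted p under 0.05 there were 1002 genes, 572 higher and 430 lower. With the experiment as a block, limma called 268 genes, 190 raised and 78 lowered (70.9% raised), among them all 8, and at an unadjusted p under 0.05 there were 1273 higher and 1046 lower. Each of the 268 differed in the same direction in all 4 experiments, which selection by the fit with the block nearly requires. In 158 of them the groups did not overlap. Over all tested genes the groups did not overlap in 6.47%, where chance gives 2.86% for arrays without regard to the pairs. These counts depend on single arrays: without the block it was 0 genes when control array 1, 2 or 3 or miR-205 array 2 or 3 was left out, 1 without control array 4, 11 without miR-205 array 1 and 15 without miR-205 array 4. With the block it was 884 genes without experiment 1, 0 without experiment 2, 49 without experiment 3 and 73 without experiment 4.

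Among the genes called only with the block, PRODH and IL6 had the largest rise and the largest fall. PRODH, proline dehydrogenase, rose by 1.85 ± 0.19 (block SE; limma adjusted p = 0.00996), and PKIA, an inhibitor of protein kinase A, by 1.71 ± 0.10 (adjusted p = 0.00226). SCEL, a precursor of the cornified envelope, rose by 1.62 ± 0.23, CDH3, which encodes P-cadherin, by 1.59 ± 0.17, ALDH1A3, a retinaldehyde dehydrogenase, by 1.53 ± 0.19, and LAD1, an anchoring filament protein, by 1.44 ± 0.10. IL6, the interleukin 6 gene, stood at -1.79 ± 0.22 (adjusted p = 0.0140), followed by the claudin gene CLDN11 at -1.46 ± 0.17 (adjusted p = 0.0127). CADM1, an adhesion molecule, fell by 1.13 on the log2 scale, NNMT, nicotinamide N-methyltransferase, by 1.11, ADGRG2 by 1.08 and CCNA1, cyclin A1, by 1.05. The values of RBPMS2, RSPO3 and BTBD3, which also fell, were -1.04, -1.02 and -0.98.

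**Figure D2:**
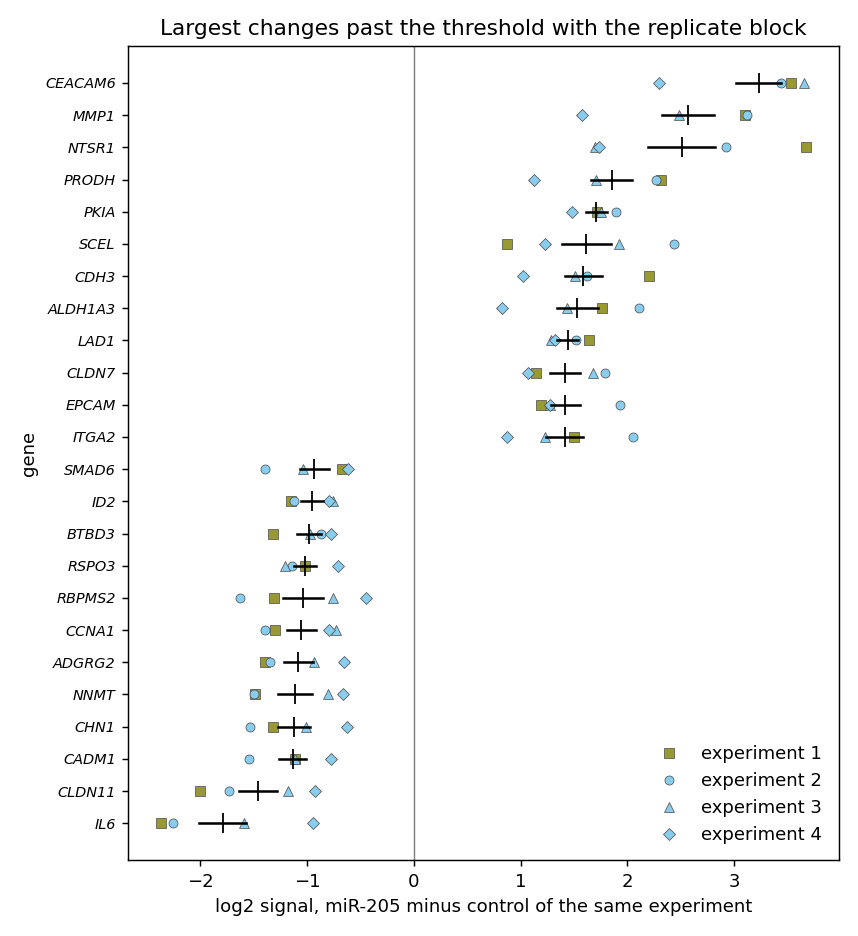
Log2 signal of miR-205 minus control of the same experiment (horizontal axis) for the 12 genes with the largest rises and the 12 with the largest falls past the threshold with the experiment as a block. Symbols are single experiments (olive squares for experiment 1), the vertical tick is the mean and the black bar its block standard error; the means run from 3.23 for CEACAM6 to -1.79 for IL6, and the genes were chosen among those with the same direction in all 4 experiments.

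The genes reported in earlier work as targets of miR-205, 8 of them in DU145 cells, tended to be lower with miR-205. Of 26 measured members, 20 had a lower mean and the median log2 difference was -0.12, or -0.08 without experiment 1. The median ran from -0.30 in experiment 1 to -0.05 in experiment 4. It was 0.20 higher on control array 1, and 0.01 higher on miR-205 array 1, than on the other arrays of the group. CHN1, a chimaerin that stimulates the GTPase activity of Rac, fell by 1.12 ± 0.15 on the log2 scale (block SE; limma adjusted p = 0.0156 with the block and 0.137 without) and E2F5, an E2F family transcription factor, by 0.75 ± 0.15 (adjusted p = 0.0464 with the block and 0.392 without). With all arrays, the other members did not pass in either fit. PRKCE, the epsilon isoform of protein kinase C, stood at -0.57 ± 0.13 (adjusted p = 0.0688 with the block), E2F1 at -0.40 ± 0.10 (0.0857) and RAB27A, a GTPase of vesicle traffic, at -0.78 ± 0.26 (0.142), or -0.40 without experiment 1. ERBB3, a receptor of the epidermal growth factor receptor family, stood at -0.38 ± 0.10 (0.0838) on its brightest probe, and its 3 probes ran from -0.38 to 0.07. LRP1, the lipoprotein receptor, went the other way at 0.71 ± 0.19 (0.0920), with a signal detected on 2 of the 4 control arrays. Without experiment 1 and with the block, 8 of 27 measured members fell and 1 rose. RAB27A (limma adjusted p = 0.0260), PRKCE (0.0074) and E2F1 (0.0480) passed there, while ERBB3 (0.0567) and LRP1 (0.0548) did not.

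Camera with its preset correlation placed this list below the other genes (adjusted p = 0.00116 over 22 lists, and 0.00572 with the block), with an adjusted p of 0.287 with an estimated correlation. Adjusted over the list alone, 5 members fell and 0 rose without the block, and 10 fell and 2 rose with it, against 0 and 2 lowered members over all probes. The list is not independent evidence of its direction, because 8 of its members were reported in DU145 cells; the 18 others had a median of -0.04 and a camera p of 0.130 (0.219 with the block).

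Epithelial junction and identity genes rose as a group. Of 27 measured members, 24 were higher with miR-205, and the median log2 difference was 0.54, between 0.39 and 0.68 in each experiment. With the block 11 members rose and 0 fell over all probes, and without it none passed. Besides CDH3, CLDN7, a tight junction claudin, rose by 1.42 ± 0.14 (block SE; limma adjusted p = 0.00992 with the block and 0.213 without). EPCAM, the epithelial cell adhesion molecule, also rose by 1.42 (adjusted p = 0.00992 with the block and 0.0894 without), and CRB3, an apical polarity protein, by 1.04 ± 0.11 (0.0105 and 0.0939). CDH1, which encodes E-cadherin, did not pass, at 0.32 ± 0.09 (adjusted p = 0.114 with the block), and was dim, with detection on 3 of the 4 control arrays. MUC1, a membrane mucin, stood at -0.77 ± 0.18 (0.0688), and MAL2, a protein of apical transport, at 0.98 ± 0.24 (0.0754) with a higher value in 3 of 4 experiments. In experiment 1 MAL2 differed by -0.05. Without that experiment and with the block, MAL2 stood at 1.34 (limma adjusted p = 0.000188) and MUC1 at -0.66 (0.0369). There 15 of 28 measured members rose and 2 fell. With all arrays, the camera adjusted p was 3.75e-12 without the block and 4.86e-12 with it, and with an estimated correlation the adjusted p was 0.287. Fry, which allows for the members' correlation, gave an adjusted p of 0.148 without the block and 0.0259 with it. Adjusted over the list alone, 11 members rose and 0 fell without the block, and 19 rose and 2 fell with it. Experiment 1 itself moved these genes: their median was 0.37 higher on control array 1, and 0.34 higher on miR-205 array 1, than on the other arrays of the group.

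Mesenchymal genes showed no common direction. The 17 measured members had a median of -0.05 (camera adjusted p = 0.571, and 0.610 with the block). ZEB1 and ZEB2, repressors of epithelial genes, were dim: ZEB1 stood at -0.42 ± 0.09 (block SE; limma adjusted p = 0.0614 with the block), and ZEB2 was detected on all 4 control arrays and on 0 of the 4 miR-205 arrays, at least 1.13-fold lower (adjusted p = 0.0693 with the block). VIM, the vimentin gene, stood at -0.09 ± 0.09 (0.606), and FN1, the fibronectin gene, was not tested because neither of its 2 probes was detected on any array. With the block TGFBI, a matrix protein induced by TGF-beta, fell by 0.59 ± 0.10 on the log2 scale (0.0365) and LOX, lysyl oxidase, rose by 0.68 ± 0.14 (0.0496). COL6A1 at 0.56 ± 0.16 (0.109) and TNC, the tenascin C gene, at 0.52 ± 0.13 (0.0832) did not pass. When adjusted over the list alone, 0 members passed without the block, and 4 rose and 6 fell with it. Without experiment 1 and with the block, 3 members rose and 4 fell over all probes, and ZEB1 and ZEB2 passed (limma adjusted p = 0.0249 and 0.0413).

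Among genes of the basement membrane LAMB3, the laminin beta-3 chain, rose by 0.79 ± 0.13 (block SE; limma adjusted p = 0.0306 with the block and 0.0880 without) on its brightest probe, 1 of 3 that ran from -0.16 to 0.79. ITGB4, the integrin beta-4 subunit of hemidesmosomes, stood at 0.77 ± 0.22 (0.106 with the block). PLEC, the plectin gene, stood at 0.54 ± 0.19 (0.158), or 0.30 without experiment 1, with a higher value in 3 of 4 experiments. The 20 measured members had a median of 0.13 and did not pass as a list (camera adjusted p = 0.0970, and 0.0679 with the block). Without the block 2 members rose when adjusted over the list alone, and with it 7 rose and 3 fell.

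Among genes of cell motility and matrix proteases, 3 proteases rose with the block and the caveola gene CAV1 fell. Besides MMP1, MMP14, a membrane-bound matrix metalloproteinase, rose by 1.37 ± 0.16 (block SE; limma adjusted p = 0.0117 with the block and 0.256 without), and PLAU, the urokinase gene, by 0.43 ± 0.09 (0.0486 and 0.315). CAV1, caveolin 1, fell by 0.64 ± 0.12 on the log2 scale (0.0442 with the block and 0.619 without). TIMP1, a protease inhibitor, stood at 0.45 ± 0.10 (0.0690 with the block) and PLAUR, the urokinase receptor, at 0.46 ± 0.13 (0.103), although 1 of its 2 probes passed. The 37 measured members had a median of 0.07 and did not pass as a list (camera adjusted p = 0.0614, and 0.130 with the block), although fry put it past the threshold without the block (adjusted p = 0.0434, and 0.0778 with the block). Adjusted over the list alone, 1 member rose without the block, and 6 rose and 1 fell with it.

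Cytokine genes and targets of NF-kB were lower on balance. Of 25 measured members 17 had a lower mean, the median was -0.16, and with the block 6 fell and 0 rose over all probes. Besides IL6, the chemokine genes CCL20, CXCL1 and CXCL5 fell by 0.88 ± 0.10, 0.56 ± 0.10 and 0.47 ± 0.09 on the log2 scale (block SE; limma adjusted p = 0.0124, 0.0369 and 0.0419 with the block). IL11 at -0.67 ± 0.17 (0.0838) and CSF2, the granulocyte-macrophage colony-stimulating factor gene, at -0.66 ± 0.19 (0.116) did not pass. The 8 members with a higher mean, of which none passed, included LIF at 0.50, TNFAIP3 at 0.46, RELB at 0.40 and NFKB2 at 0.32. The lower balance therefore does not hold for all NF-kB targets of the list. Camera gave an adjusted p of 0.0306 without the block and 0.00787 with it, and 0.727 with an estimated correlation. Without the block 1 member fell when adjusted over the list alone, and with it 11 fell and 3 rose. The call without the block was lost when control array 1 or miR-205 array 2, 3 or 4 was left out (highest adjusted p = 0.219). The list's median was 0.36 higher on control array 1, and 0.60 higher on miR-205 array 1, than on the other arrays of the group.

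The list of TGF-beta targets was also lower. The list also holds ligand and receptor genes of the pathway, and whether its members respond to TGF-beta in these cells was not tested. The 22 measured members had a median of -0.38, between -0.39 and -0.26 in each experiment, and 15 had a lower mean. With the block 4 fell and 0 rose over all probes: ID2, an inhibitor of DNA binding, by 0.96 ± 0.11 on the log2 scale (block SE; limma adjusted p = 0.0105), the inhibitory SMAD gene SMAD6 by 0.93 ± 0.14 (0.0229), the thrombospondin gene THBS1 by 0.90 ± 0.17 (0.0462), and TGFBI. CCN2, connective tissue growth factor, at -0.93 ± 0.21 (0.0654) and ID1 at -0.70 ± 0.14 (0.0527) did not pass. The camera adjusted p was 0.000641 without the block and 0.000292 with it, and 0.287 with an estimated correlation. Adjusted over the list alone, 7 members fell and 0 rose without the block, and 13 fell and 4 rose with it. Compared with the other arrays of the group, the list's median differed by -0.17 on control array 1 and by -0.51 on miR-205 array 1.

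Interferon-stimulated genes did not pass camera as a list. The 33 measured members had a median of -0.04 (camera adjusted p = 0.719, and 0.599 with the block), but without control array 1 the list turned higher and passed (median 0.22, adjusted p = 0.00492). With the block the antiviral membrane protein genes IFITM2 and IFITM3 fell by 0.81 ± 0.10 and 0.68 ± 0.11 on the log2 scale (block SE; limma adjusted p = 0.0140 and 0.0261), and ISG20, an antiviral exonuclease, rose by 0.86 ± 0.09 (0.0103). HERC5 at -0.45 ± 0.19 (0.229), or -0.18 without experiment 1, and OAS3 at 0.43 ± 0.11 (0.0878) did not pass. With the block 2 members rose and 3 fell when adjusted over the list alone, and without it 0 passed. These genes differed more between experiments: their median was 0.78 higher on control array 1, and 0.44 higher on miR-205 array 1, than on the other arrays of the group.

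Genes of the G2 and M phases were lower in 33 of 37 cases, with a median of -0.19, and no single member passed in either fit. CENPF, a kinetochore protein, stood at -0.61 ± 0.16 (block SE; limma adjusted p = 0.0901 with the block) and ECT2, an exchange factor of cytokinesis, at -0.69 ± 0.26 (0.188), or -0.30 without experiment 1. The camera adjusted p was 0.000338, and 2.52e-05 with the block, but the adjusted p was 0.727 with an estimated correlation and 0.403 when miR-205 array 1 was left out. Without both arrays of experiment 1 the list passed again, with a median of -0.13 and an adjusted p of 0.00488 without and with the block. On miR-205 array 1 the list's median differed by -0.63 from the other miR-205 arrays, and on control array 1 by -0.33 from the other controls. The 40 genes of the G1/S transition had a median of -0.04 (camera adjusted p = 0.160, and 0.153 with the block), with EZH2, the histone methyltransferase of polycomb, at -0.47 ± 0.11 (limma adjusted p = 0.0796 with the block). In both lists 0 members passed when adjusted over the list alone. The 33 genes of CDK inhibition, p53 response and apoptosis had a median of 0.06 (camera adjusted p = 0.809, and 0.599 with the block). Of these BIK, a pro-apoptotic BCL2 family member, rose by 0.66 ± 0.12 with the block (0.0420), while BID at -0.43 ± 0.10 (0.0680) and SESN2, a stress-induced sestrin, at 0.75 ± 0.33 (0.248), or 0.26 without experiment 1, did not pass. Adjusted over that list alone, 0 members passed without the block, and 1 rose and 1 fell with it.

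The lists of hypoxia and of lipid synthesis passed with the block but, as processed here, not without it. Some other settings without the block let them pass, such as leaving out control array 1 (adjusted p = 0.0106 and 0.00129). With the block the hypoxia call was lost under median scaling (0.127) and without experiment 3 (0.0786). Genes of hypoxia and glycolysis (30 measured, median 0.03, mean 0.13) had a camera adjusted p of 0.134 without and 0.0448 with the block. Of these ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose by 1.03 ± 0.11 (block SE; limma adjusted p = 0.00996 with the block; its 2 probes gave 0.43 and 1.03), HK2, hexokinase 2, by 0.83 ± 0.10 (0.0124), and LOX by the value given above. SLC2A1, the glucose transporter, at -0.57 ± 0.17 (0.126) and NDRG1 at 0.54 ± 0.11 (0.0576) did not pass. When adjusted over the list alone, 2 members rose without the block and 6 with it. Genes of cholesterol and fatty acid synthesis were higher in 24 of 32 cases, with a median of 0.22 and a camera adjusted p of 0.0614 without and 0.00458 with the block. No single member passed, also when adjusted over the list alone. FADS2, a fatty acid desaturase, stood at 0.51 ± 0.23 (limma adjusted p = 0.250 with the block), or 0.19 without experiment 1. DHCR7, an enzyme of cholesterol synthesis, stood at 0.47 ± 0.16 (0.147), or 0.30 without experiment 1. With an estimated correlation and the block, both lists had an adjusted p of 0.411. Their medians were 0.14 and 0.41 higher on control array 1, and 0.26 and 0.46 higher on miR-205 array 1, than on the other arrays of the group.

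Further cellular lists moved little as processed here. Ribosomal protein genes (43 measured, median -0.10, 33 lower) had a camera adjusted p of 0.0264, and 0.0365 with the block, but the adjusted p was 0.287 with an estimated correlation and 0.168, 0.0632 and 0.0778 when miR-205 array 1, control array 2 or control array 4 was left out. Their median was -0.20 with the block and median scaling (camera adjusted p = 2.85e-08), and -0.03 without experiment 1 (0.0934 without the block and 0.130 with it). No member passed: RPL10A stood at -0.44 ± 0.28 (block SE; limma adjusted p = 0.404 with the block), or -0.02 without experiment 1, and RPS23 at -0.41 ± 0.10 (0.0796). Genes of the mitochondrial respiratory chain (36 measured, median -0.04) had a camera adjusted p of 0.0614, and 0.0877 with the block. NDUFV1, a subunit of complex I, fell by 0.47 ± 0.09 on the log2 scale with the block (0.0486), while NDUFS1 at -0.33 ± 0.09 (0.0988) and SDHA at -0.25 ± 0.11 (0.252), or -0.13 without experiment 1, did not pass. Genes of autophagy and the lysosome (37 measured, median 0.05) had a camera adjusted p of 0.305, and 0.175 with the block, with WIPI1, an autophagosome protein, at 0.55 ± 0.12 (0.0624). The 13 genes of the microRNA machinery had a median of 0.03 (camera adjusted p = 0.825, and 0.744 with the block), with TNRC6A at 0.28 ± 0.12 (0.211) and RAN at -0.21 ± 0.12 (0.359), or -0.07 without experiment 1. Genes of the unfolded protein response (29 measured) had a median of 0.06 and a mean of 0.08, or -0.09 and -0.04 without experiment 1. With all arrays camera set them below the other genes without the block and above them with it (adjusted p = 0.953 and 0.683). CHAC1 stood at 0.54 ± 0.35 (0.406), or 0.01 without experiment 1. Adjusted over each list alone, 0 members passed without the block, and with it 6 autophagy genes rose and NDUFV1 fell.

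**Figure D3:**
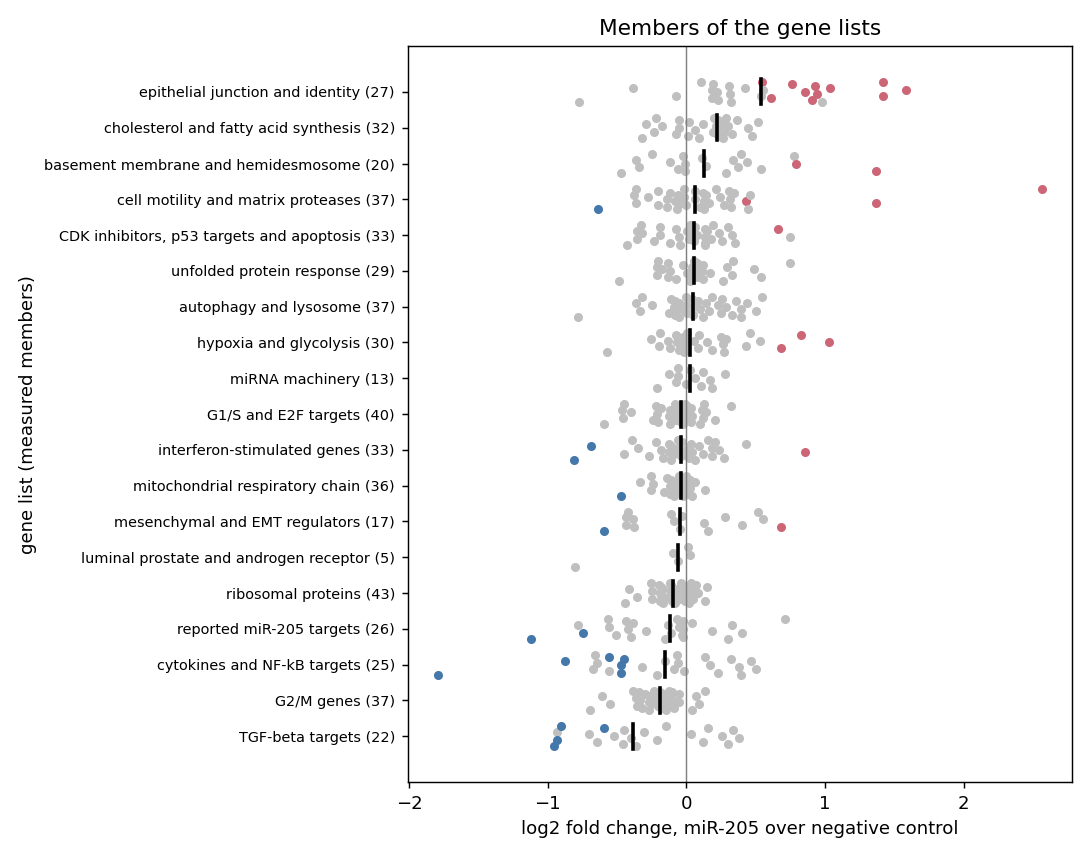
Log2 fold change of miR-205 over negative control (horizontal axis) for the measured members of 19 gene lists (vertical axis, number of measured members in brackets). Points are genes, red where raised and blue where lowered past the threshold with the experiment as a block and grey otherwise, and the black bar is the list's median, from 0.54 for epithelial genes to -0.38 for TGF-beta targets.

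Markers of other cell types were mostly not measured. Of 15 leukocyte markers 4 were measured, with a median of 0.58 (camera adjusted p = 0.0614, and 0.0952 with the block). CD68, a lysosomal membrane protein that many cell types make, rose by 0.87 ± 0.12 (block SE; limma adjusted p = 0.0158 with the block), while CD74, the invariant chain, at 0.60 ± 0.13 (0.0619) and ITGB2, the integrin beta-2 subunit, at -0.59 ± 0.12 (0.0573) did not pass. Adjusted over that list alone, 2 members rose without the block, and 3 rose and 1 fell with it. Of 14 markers of luminal prostate and the androgen receptor 5 were measured, with a median of -0.06 (camera adjusted p = 0.357, and 0.403 with the block). KLK3, which encodes prostate-specific antigen, stood at -0.80 ± 0.20 (0.0811), on a probe whose specificity was not tested, and FKBP5 at -0.09 ± 0.12 (0.695). Adjusted over that list alone 1 member fell with the block and 0 passed without it. Single measured markers of fibroblasts, FBLN1 at 0.04 ± 0.12 (0.890; its 3 probes ran from -0.39 to 0.04), and of endothelium, EGFL7 at 0.07 ± 0.12 (0.794), did not pass; their lists had camera adjusted p of 0.953 and 0.882, and 0.870 and 0.791 with the block.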

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

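The tests on experiment 1 in the next paragraph, except the slope, were chosen after the result was seen; the splits of the samples and the tests on the share of raised genes were planned, while the intervals of these shares were added after the shares were seen.

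The arrays of experiment 1 stood apart, since the mean squared deviation from the group mean was 0.0413 higher on control array 1 than on the nearest control, and 0.130 higher on miR-205 array 1 than on the nearest miR-205 array. A dim array is argued against: control array 1 deviated 2.60 times as much as the dimmest control, and over the brightest 25% of probes miR-205 array 1 deviated 4.08 times as much as the mean of the other 3. A stronger miR-205 response cannot account for control array 1, which deviated 2.17 times as much as the highest other control. For miR-205 array 1 such a response cannot be told apart, because the slope of experiment 1 on the other experiments over 873 genes was 1.00 (95% interval 0.948 to 1.06). Of these, genes raised in the other experiments had a median of 0.56 in experiment 1 and 0.48 in the others. The lowered genes had -0.36 and -0.44. The genes were chosen by the other experiments, which can lower the slope, and the interval treats them as independent. A difference between experiments shared by both transfections stays open: the deviations of the 2 arrays correlated across probes at 0.624, which is consistent with conditions of that experiment, such as the state of the cells, that no label describes. Such sharing is not particular to experiment 1, since the arrays of experiments 2 and 4 correlated at 0.611 and 0.572.

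More genes rose than fell with the experiment as a block (190 against 78), while at an unadjusted p under 0.05 the numbers were 1273 and 1046. Normalization between arrays cannot be excluded: the lowest share of raised genes over median scaling, no background correction and the authors' processed values was 70.7% (95% binomial interval 65.2 to 75.7; bound set beforehand 60%), but all 3 put the arrays at one level. Compression of falls near background cannot be excluded by that bound: 68.5% of the called genes brighter than the median were raised, but the interval, 59.7 to 76.3, reaches under 60%. For experiment 1 as the whole cause, the test set beforehand went against it. Among the same number of genes ranked by p without it, 67.9% were raised (62.0 to 73.5), above the 60% bound. A wider exclusion is not drawn. At the threshold the share there was 56.8% (502 against 382), and at an unadjusted limma p under 0.05 there were 1433 higher and 1352 lower. All of these intervals treat genes measured on the same arrays as independent, so they can be too narrow. That the mimic itself raises more genes stays open as a hypothesis, since no other microRNA was tested.

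Of the 35 splits of the 8 arrays into groups of 4, 2 gave at least as many genes as the real one without the block, the real one included (8 genes; highest other 13), so chance cannot be excluded; the same 2 splits hold for the 8 raised genes. The split with 13 genes sets experiments 1 and 4 against 2 and 3, so it follows the experiments. With 0 lowered genes 35 of 35 splits were equal. Of the 8 splits that part all 4 pairs of arrays, as the real one does, the other 7 called 0 genes, while the 24 that part 2 pairs called 0 and the 3 that part none called up to 13. With the block the real labels gave 268 genes and the highest of the other exchanges of labels within experiments gave 0; the 8 exchanges, of which 1 gave as many, are too few for a share under 0.05.

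Without the block the number of lists past camera did not exceed what other splits give: 16 of 35 splits had 6 or more (highest other 11). With the block the real labels passed 8 lists and the other 7 exchanges within experiments passed 1 to 7, too few exchanges for a share under 0.05. For the epithelial list 1 of the 35 splits, the real one, gave a camera p as small (1.70e-13, lowest other 1.25e-10). That is the smallest share that 35 splits can give. It was read for each of the 6 lists that passed, without correction, over splits that ignore the pairs, so chance was not excluded. For the other lists that passed, more splits gave a p as small. It was 2 of 35 for reported targets (real 0.000211, lowest other 3.66e-05) and 2 of 35 for TGF-beta targets (8.74e-05 and 3.97e-06). It was 4 of 35 for ribosomal proteins (0.00600 and 0.000133), 12 of 35 for cytokines (0.00834 and 1.44e-08) and 17 of 35 for G2/M genes (3.07e-05 and 1.43e-15). Over the 8 exchanges within experiments, with the block, the real labels alone gave a p as small for epithelial genes (2.21e-13; lowest other 1.87e-06), reported targets (0.00130; 0.00303), TGF-beta targets (3.98e-05; 0.000601) and cytokines (0.00214; 0.00504), while 2 exchanges did for ribosomal proteins (0.0116; 0.00142) and 4 for G2/M genes (2.29e-06; 3.07e-10). For the lists called with the block alone, 2 exchanges each gave a p as small, for lipid synthesis (0.000832; 0.000127) and hypoxia (0.0163; 0.00412), and over the 35 splits without the block 18 and 13 did. These exchanges are too few for a share under 0.05. The 3 splits that part no pair, and so set whole experiments against each other, passed 7 to 9 lists.

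Of 194 groups of 4 values examined, 18 had an array far from the others, 10 of them on miR-205 array 1, 5 on control array 1 and 3 elsewhere; chance marks about 5%. The value given is the distance to the nearest array of the group in log2 units. On miR-205 array 1, RAB27A was lower by 1.14, CAV1 by 1.26, ZEB2 by 0.373, ZEB1 by 0.360, RAN by 0.813 and FKBP5 by 0.489. On the same array CSF2 was higher by 0.765, CD74 by 1.53 and ISG20 by 1.33. On control array 1, MUC1 was higher by 1.98, HERC5 by 1.26, BIK by 1.09 and CEACAM6 by 0.964. ADGRG2 was higher by 0.923 on miR-205 array 4, NDUFV1 was lower by 0.182 on control array 3, and ITGA2 was lower by 0.533 on control array 2.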

How the results depend on the processing

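Alternatives named with the block other than the plain block, those that leave out an experiment, and the random effect were chosen after seeing the data; the others were planned. A block by slide or scan was not run, since no file gives slides or scans, and neither were seed matches in 3' untranslated regions, for which no transcripts were used here. Without the detection filter the genes tested went from 10982 to 18122 and 0 passed.

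In the alternatives that tested them none of the 8 genes that passed without the block turned its direction, and leaving out control array 1 turned the interferon list higher (median 0.22, adjusted p = 0.00492). The same number of calls, within 1.5 times, came with probes detected on all 8 arrays (6 genes), the mean of a gene's probes (9) and a 1.5-fold minimum (8).

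Without the block, 5 genes passed with no background correction (all raised), 26 with median scaling (all raised), 1 with an offset of 50 (raised), 1 in the authors' processed values (raised), 14 with a trended robust prior (all raised), 0 at an adjusted p under 0.01, and 0 without the detection filter (0 raised; 1547 at an unadjusted p under 0.05). Array weights gave 283 genes, 181 raised and 102 lowered. Leaving out 1 array in turn gave 0 to 15 genes, 0 to 13 raised and 0 to 2 lowered. Without experiment 1 there were 42 genes, 38 raised and 4 lowered.

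With the experiment as a block (replicate block) there were 268 genes, 190 raised and 78 lowered. As a random effect it gave 377 (245 and 132), with median scaling 417 (333 and 84), with no background correction 307 (217 and 90), and the authors' processed values 105 (80 and 25). Without experiment 1 it gave 884 (502 and 382, 56.8% raised), which include all 268 in the same direction, from arrays that the full fit also used. Without replicate 2 it gave 0 (0 raised), without replicate 3 49 (40 and 9), and without replicate 4 73 (56 and 17). Other settings kept fewer of the 268. It was 211 as a random effect, 257 with median scaling, 243 with no background correction and 100 in the authors' processed values. It was 48 without replicate 3 and 71 without replicate 4. Array weights without the block kept 178. The cause of these differences was not tested, beyond the fewer arrays or probes some settings hold.

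The adjusted p of the lists moved across the threshold as follows. With an estimated correlation it was 0.287 for reported targets, epithelial genes, TGF-beta targets and ribosomal proteins, and 0.727 for cytokines and G2/M genes. The members' correlation alone does not account for all such rises. Motility genes, with an estimated 0.00268, under the preset 0.01, went from an unadjusted camera p of 0.0259 to 0.0478. Array weights gave 0.0221 for motility, 0.133 for G2/M, 0.00863 for hypoxia and 0.102 for ribosomal proteins. Median scaling gave 0.0237 for cholesterol synthesis and 0.00428 for the respiratory chain, no detection filter 0.00997 for motility, 0.0707 for cytokines and 0.0241 for the respiratory chain, and the authors' processed values 0.0534 for cytokines and 0.0491 for the respiratory chain. Without experiment 1 and without the block it was 0.0170 for cholesterol synthesis, 0.0154 for hypoxia and 0.0934 for ribosomal proteins, and with the block 0.00395, 0.00397 and 0.130. The plain block gave 0.00458 for cholesterol synthesis and 0.0448 for hypoxia, and changed no other call of a list. With the block and median scaling, cholesterol synthesis and the respiratory chain both had 0.00294. With the block and no background correction, cholesterol synthesis had 0.00286 and hypoxia 0.0398. With the block in the authors' processed values it was 0.00895 for cholesterol synthesis and 0.0489 for hypoxia and the respiratory chain. With the block and without replicate 2, cholesterol synthesis and hypoxia had 0.0190, without replicate 3 the basement membrane had 0.0361 and cholesterol synthesis 0.00161, and without replicate 4 the basement membrane and cholesterol synthesis had 0.0300, hypoxia 0.0411, ribosomal proteins 0.0729 and the respiratory chain 0.0413.

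Leaving out 1 array in turn, without the block, the adjusted p ran from 6.48e-13 to 2.00e-08 for epithelial genes, 0.000114 to 0.0308 for reported targets and 4.82e-05 to 0.0103 for TGF-beta targets, all past the threshold. It crossed the threshold for G2/M (1.38e-07 to 0.403), cytokines (9.76e-05 to 0.219), ribosomal proteins (0.00780 to 0.168), G1/S (0.0159 to 0.928), autophagy (0.0392 to 0.881), basement membrane (0.0283 to 0.393), motility (0.0395 to 0.149), cholesterol synthesis (0.00129 to 0.593), hypoxia (0.0106 to 0.394), interferon-stimulated genes (0.00492 to 0.945), the respiratory chain (0.0131 to 0.931) and leukocyte markers (0.0225 to 0.383).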

Other observations

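Genes of stratified epithelium not yet described were examined as a further group, in a test chosen after the result was seen, because SCEL and LAD1 were among the largest rises. The list has 51 genes of basal and differentiating stratified epithelium, written from background knowledge. Leaving out members of the fixed lists, genes named by the rule and genes seen before, 16 of 43 were measured, with a median log2 difference of 0.20. With the block GJB2, a gap junction connexin, rose by 0.61 ± 0.11 (limma adjusted p = 0.0378), PPL, periplakin, by 0.80 ± 0.13 (0.0332) and KLF5, an epithelial transcription factor, by 0.46 ± 0.09 (0.0464), each in 4 of 4 experiments. LCN2, lipocalin 2, fell by 0.55 ± 0.10 on the log2 scale (0.0382), and SLPI stood at -0.79 ± 0.17 (0.0610). Among the genes seen before the list was written, KRT15, a basal keratin, stood at 1.00 ± 0.16 (0.0279), SERPINB5, maspin, at 0.85 ± 0.11 (0.0148) and LYPD3 at 0.86 ± 0.12 (0.0171).

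A candidate explanation is that miR-205 moves these cells toward genes of stratified epithelium as well as of epithelial junctions. Camera with the block gave a p of 0.0383 for the 16 genes, in the predicted direction, and 0.113 with an estimated correlation. The hypothesis was found and tested on the same arrays, and members that fell, such as LCN2, go against it.

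KLK3, a gene of the androgen-responsive luminal prostate, was detected on all 8 arrays, with a mean log2 signal of 7.84 ± 0.40 in controls and 7.04 ± 0.61 with miR-205 (SD, n = 4). The specificity of its probe was not tested, so no level of the transcript is drawn from it.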
